A study of Drosophila melanogaster with 3 samples.

How the data were processed

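Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos collected from 0 to 24 hours of development, with both sexes pooled. The flies carried a transgene for the homeobox transcription factor NK7.1 fused at its C-terminus to eGFP, and chromatin was precipitated with an antibody against GFP, per the labels. Chromatin was fragmented by sonication, with a size range given as 200 to 800 in the labels. The series holds 3 biological replicates of this 1 group, numbered in the labels. Libraries of an untagged line, of input chromatin or of another factor were not analysed here, so the comparisons are between replicates and between peaks of different rank.

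The authors deposited peak lists in narrowPeak format on the dm6 and dm3 assemblies, per the text listings deposited with each library. Peaks had been called once per replicate and once on the pooled alignments of the 3 libraries, in each case against a control, per the same listings. From the replicate and pooled lists the authors had derived a list thresholded by the irreproducible discovery rate (IDR), a measure of rank agreement between replicates, and this list is called the reproducible set here. The authors label it the optimal list. It holds the strongest peaks of the pooled list, so membership alone does not show that a peak ranked high in each replicate. The aligner and the peak caller are not given in the sources used here. The deposited signal value of each peak is a score on the peak caller's own scale, and whether it was scaled for depth is not given in the sources used here. The deposited −log10 q-value of each peak was capped, and 1276 of the 2475 reproducible dm6 peaks held the largest value of 3.41, so peaks were ranked by the signal value. Both values are the authors' own and were used only to rank and describe peaks within a list.

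The lists hold no read counts, so the depth of the libraries is unknown and no depth enters any error given here. Intervals and p-values cover the counting of peaks, summits or genes only. Peaks and genes are not independent replicates, and neighbouring genes can share a peak. The spread between embryo collections is given as the mean and SD over the 3 replicates, each with its own top 2475 peaks.

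Coordinates are on dm6 and 1-based. Sequences came from the Release 6 assembly and gene models from the Ensembl 115 annotation of the same assembly, on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X. The dm3 lists were used for counts only and no coordinates were converted. A peak of the reproducible set counted as supported by a replicate when at least 1 bp of it was overlapped by one of that replicate's top 2475 peaks, 2475 being the size of the reproducible set. Chance overlap came from 100 random placements of the peaks within their own arms, and from 20 placements for pairs of replicates. Low-ranked peaks, the background for chromosomes and genomic features, were the 23895 peaks of the pooled list that overlapped no reproducible peak. The authors label the pooled list as peaks and background for input to IDR. Low-ranked peaks therefore include entries that need not be binding sites. A summit was assigned in this order to a window of 1 kb on either side of a transcription start site (TSS), a 5' UTR, a coding exon, a 3' UTR, an intron or noncoding exon, or intergenic sequence. A gene counted as having a peak when a reproducible summit lay in the gene or within 2 kb of it.

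Shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the arms, features or gene lists of each family and a threshold of 0.05. Against arm length the test was an exact binomial test, and with gene length as a covariate it was a likelihood-ratio chi-square test in a logistic model across genes. Odds ratios have Wald 95% intervals and shares have exact Clopper-Pearson 95% intervals. For motifs at summits against flanks, the interval of the odds ratio came instead from an exact binomial interval. That interval covers the windows where only the summit or only the flank held the motif. Motifs were counted on either strand within 50 bp of each summit and in a window of the same width 500 bp to one side, the side being drawn at random, and compared by the exact McNemar test, two-sided, with adjustment over the 5 motifs or over all 2080 6-mers. Against low-ranked summits the motif shares were compared by Fisher's exact test. The analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9.

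The main tests, 13 gene lists and all alternatives except those named as chosen later were fixed before the data were examined. The lists cover NK-like homeobox genes, the Hox complex, segmentation, mesoderm and muscle regulators, muscle structural genes, neural progenitor and glial regulators, neuron differentiation, tracheal and ectodermal regulators, the Notch pathway and E(spl) complex, signalling ligands and receptors, ribosomal proteins, odorant and gustatory receptors, and cuticle proteins. All list members were matched to the annotation by current symbol, or by a synonym held by 1 gene alone, so that Dl of the Notch list is Delta and h of the segmentation list is hry. A first run had matched Dl to dorsal through a shared synonym, and with that gene the Notch list had passed the threshold. Named items followed a rule fixed at the same time: every reproducible peak in or within 2 kb of NK7.1, the 15 reproducible peaks with the highest signal that were supported by all 3 replicates, and for each list up to 4 members with the strongest peak. Of a top peak the rule names the genes whose body holds the summit, or else the gene with the nearest TSS. Of the items this rule picks, 1 was left out of the text.

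The functions were tested on simulated data before use. A planted overlap of 60% between lists of 2475 peaks was recovered as 60.4%. A planted odds ratio of 2.25 for near-TSS summits among 26951 summits was recovered as 2.25, and one of 1.50 for the X chromosome as 1.61. Of simulated gene lists with a raised share, 100% were called over 13945 genes, and 7.50% of the unchanged lists tested with them were called. Of 400 further unchanged lists, 2.75% had an unadjusted p under 0.05. A motif planted in 10% of 2475 windows ranked 1 of 2080 6-mers.

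Alternatives varied the number of peaks per replicate, the overlap rule, the TSS, gene and motif windows, the backgrounds, gene length as a covariate, the reproducibility threshold (the 1237 strongest peaks) and the replicates used. For arms, features, gene lists and motifs, leaving out replicate 1, 2 or 3 kept the 1642, 1659 or 1657 reproducible peaks supported by both others. Peaks were not called anew, so these subsets still rest on the pooled libraries of all 3 replicates. The comparison of the 2 builds by rank was limited to the chromosome arm, because peak widths differed between builds and peaks could not be matched without converting coordinates.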

Results

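Binding of the homeobox factor NK7.1 was mapped by ChIP-seq in whole embryos with an eGFP-tagged protein, in 3 biological replicates of 1 group. On dm6 the replicate lists held 25801, 30000 and 30000 peaks, the pooled list held 26951 and the reproducible set held 2475. The lowest −log10 q-values were 0.0177, 0.0530 and 0.0670 in the replicate lists and 0.0177 in the pooled list, against 2.74 in the reproducible set. The replicate and pooled lists thus extend into background, and their sizes are not counts of binding sites. On dm3 the pooled list held 23573 peaks and the reproducible set 2273. In both builds the reproducible set was made up of exactly the strongest peaks of the pooled list, 9.18% of it on dm6 and 9.64% on dm3. The 6 arms held similar numbers in both builds, with 594 reproducible peaks on 3R in dm6 and 536 in dm3, and 453 and 417 on X. Among the first 200 ranks the same arm stood at the same rank in both builds 104 times, against 40.3 expected by chance. The median peak width on dm6 was 420 bp. Signal values in the reproducible set ran from 92.5 to 1837. The number of reads behind a peak is unknown.

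The strongest peaks were shared by all replicates, and 76.0% of the summits at ranks 1 to 100 lay within 1 kb of a TSS. The peak with the highest signal, 1837, lay on 2L at 480870 to 481298 in an intron of ush, which encodes a zinc-finger cofactor of GATA factors, with the nearest TSS, that of cbt, 1394 bp away, and it ranked 1 in each replicate. The next, on X at 2703687 to 2704081 with a signal of 1580, lay 33 bp upstream of a TSS of Ugalt, a UDP-galactose transporter gene, and ranked 5, 2 and 2 in replicates 1, 2 and 3. A peak on 2R at 22514092 to 22514490 lay in an intron of px, 207 bp from a TSS, with a signal of 1482. On 3L at 19590432 to 19590803 the nearest gene was CG14100, whose TSS was 88 bp away. The remaining named peaks lay in introns of CG11050, PNPase, the Polycomb group gene ph-p, the kinase gene Lk6 and CG32772, in the 5' UTRs of CG1888 and of Chro, which encodes a chromodomain protein, in noncoding exons of lncRNA:Vinr and lncRNA:CR31840, and 141 bp and 113 bp from the TSSs of mRpL41 and Art3. The signals of all 15 named peaks ran from 896 to 1837.

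The first comparison asked how far each replicate on its own recovered the reproducible set. Of the 2475 reproducible peaks, 2021 (81.7%, 95% interval 80.1 to 83.2%) were overlapped by a top 2475 peak of replicate 1, 1966 (79.4%, 77.8 to 81.0%) by one of replicate 2 and 2000 (80.8%, 79.2 to 82.3%) by one of replicate 3. All 3 replicates supported 1429 peaks (57.7%, 55.8 to 59.7%), and at least 2 supported 2100 (84.8%, 83.4 to 86.2%). No replicate supported 17 peaks. Random placement gave 0.710% in all 3 replicates on average and 1.13% at most over 100 placements. Support fell with rank: 100% of ranks 1 to 275 and 5.45% of ranks 2201 to 2475 were supported by all 3. The last ranks lie at the cutoff of 2475 applied to each replicate, where single replicates supported 44.7 to 48.7%. A fall there is built into the criterion, and with the doubled number of top peaks 86.1% of the whole set was supported by all 3. Against the full replicate lists 2458 peaks (99.3%) were overlapped in all 3, while random placement gave 15.5% per replicate with those lists. The reproducible set was made from these same libraries, so the overlap is not an independent check of it.

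**Figure D1:**
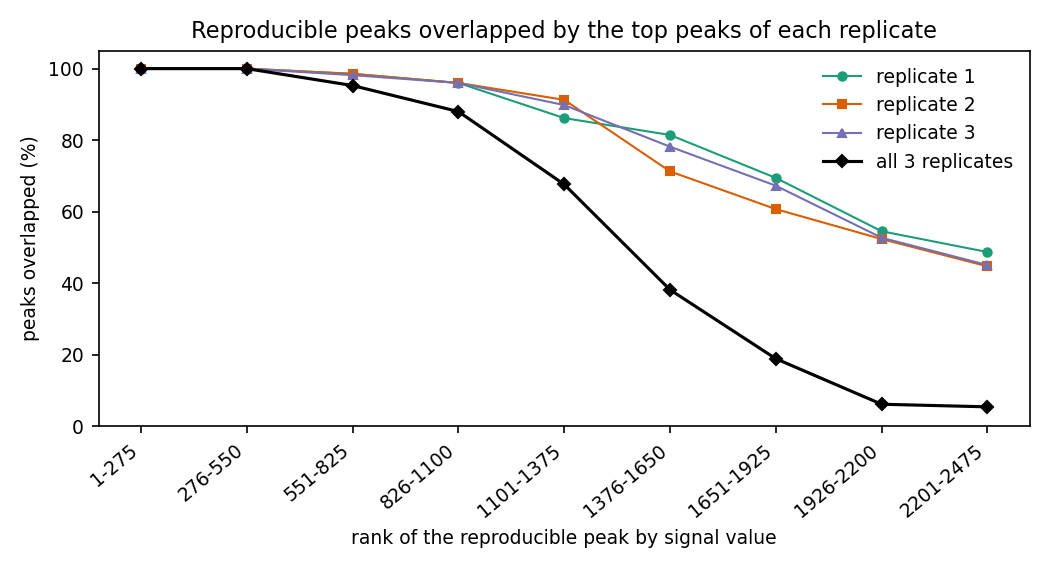
Share of reproducible peaks, in percent, overlapped by a top 2475 peak of each replicate (coloured lines) and of all 3 replicates (black), by rank of signal value on the horizontal axis. Support by all 3 fell from 100% at ranks 1 to 275 to 5.45% at ranks 2201 to 2475, which lie at the cutoff applied to each replicate.

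Between pairs of replicates, 67.8 to 69.3% of the top 2475 peaks of one were overlapped by the top 2475 of another, with a mean of 68.7% against 1.47% for random placement. Spearman's rho of the signal values over mutually overlapping peaks was 0.719 to 0.725 in the 3 pairs. This is a correlation across peaks, which are not independent replicates.

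At the NK7.1 gene itself, 7 reproducible peaks lay in the gene or within 2 kb of it. NK7.1 (FBgn0024321) lies on the minus strand of 3R from 14329413 to 14372951. Its strongest peak, at 14373171 to 14373590 with a signal of 321, lay 430 bp upstream of an NK7.1 TSS, and its overlapping peaks ranked 308, 201 and 157 in replicates 1, 2 and 3. A second peak upstream of a start site lay in an intron at 14370530 to 14370949, 732 bp from a TSS, with a signal of 163, and a weaker one at 14369734 to 14370153 lay in the 5' UTR with a signal of 96.7. There were 3 further intronic peaks, at 14356595 to 14357014, 14351371 to 14351790 and 14357439 to 14357858, with signals of 112, 107 and 102. The last of the 7, at 14327674 to 14328093 with a signal of 241, lay beyond the 3' end of NK7.1 and 167 bp upstream of the TSS of spn-B. The top 2475 peaks of each replicate alone held 5 ± 1 peaks (SD, n = 3) in this window. Only the peaks with signals of 321, 241 and 163 were supported by all 3 replicates. The peak with a signal of 107 was supported by replicate 2 alone, and that with 96.7 by replicate 3 alone.

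**Figure D2:**
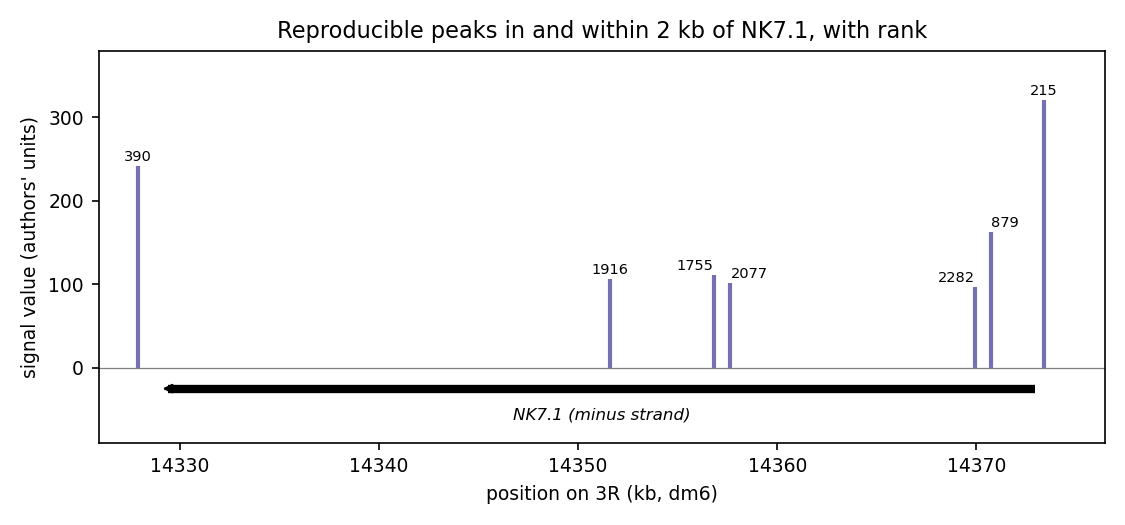
Reproducible peaks in and within 2 kb of NK7.1 on 3R (dm6, position in kb), with the authors' signal value on the vertical axis and the rank in the reproducible set above each line. The 2 strongest, with ranks 215 and 390, stand at the ends of the gene, and the latter lies 167 bp upstream of spn-B.

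Reproducible summits lay near gene starts. Within 1 kb of a TSS there were 1623 of 2475 reproducible summits (65.6%) and 10380 of 23895 low-ranked summits (43.4%), an odds ratio of 2.48 (95% interval 2.27 to 2.71, exact adjusted p = 4.99e-98), while these windows cover 23.6% of the genome. The replicates' own top peaks gave 66.2 ± 1.46% (SD, n = 3). Summits in coding exons away from a TSS were nearly missing from the reproducible set, with 5 summits (0.202%) against 11.1% of low-ranked ones (odds ratio 0.0161, exact adjusted p = 3.42e-110). Introns held 25.4% against 29.6% (odds ratio 0.811, exact adjusted p = 1.36e-05), and intergenic sequence 8.12% against 13.5% (odds ratio 0.565, exact adjusted p = 1.96e-15). The 3' UTR share was 0.566% against 1.81% (odds ratio 0.309, exact adjusted p = 6.31e-07). The 5' UTR share was 0.121% against 0.485% (odds ratio 0.249, exact adjusted p = 0.00656), but only 3 reproducible summits lay there. The 5' UTR difference did not pass the threshold with a TSS window of 500 bp (exact adjusted p = 0.118) or 2 kb (exact adjusted p = 0.0589), for the 1237 strongest peaks (exact adjusted p = 0.132) or without replicate 1 (exact adjusted p = 0.0903). The intron difference did not pass it with 500 bp (exact adjusted p = 0.239). The near-TSS share was 76.0% at ranks 1 to 100, 62.3% at ranks 1651 to 2475, 61.8% at ranks 2476 to 5000 just outside the set, and 34.9% at the end of the pooled list.

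**Figure D3:**
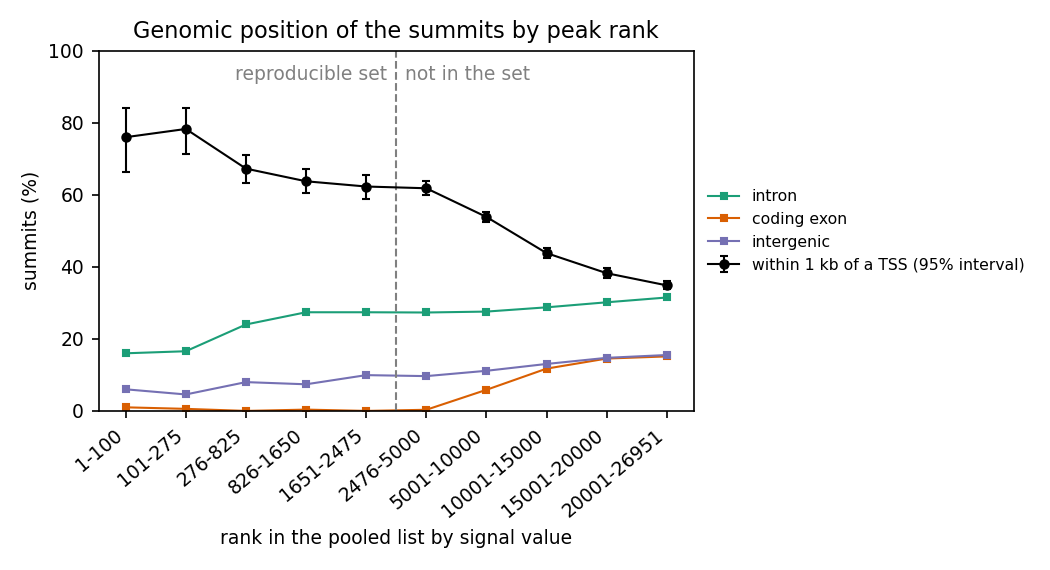
Share of summits, in percent, within 1 kb of a TSS (black, with exact 95% intervals) and in introns, coding exons and intergenic sequence (coloured), by rank in the pooled list. The near-TSS share fell from 76.0% at ranks 1 to 100 to 34.9% at the end of the list, with no step at the dashed line that ends the reproducible set.

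Along the chromosomes, X held 453 reproducible peaks (18.3%) against 14.9% of the low-ranked peaks, an odds ratio of 1.28 (95% interval 1.15 to 1.42, exact adjusted p = 8.20e-05). Per length X held 19.2 reproducible peaks per Mb, close to 19.3 on 2L and 18.5 on 3R, and against arm length its odds ratio was 1.05 (exact adjusted p = 0.684). Chromosome 4 held 10 peaks, 7.42 per Mb. Its odds ratio of 0.501 against low-ranked peaks did not pass the threshold (exact adjusted p = 0.0855), and against arm length it was 0.399 (exact adjusted p = 0.00704). For 2L, 2R, 3L and 3R the odds ratios were 0.933 to 0.976 and none passed the threshold. In the replicates' own top peaks X held 17.8 ± 0.589% (SD, n = 3).

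Genes for ribosomal proteins carried peaks far more often than other genes. Of 92 genes, 63 (68.5%) had a reproducible summit in the gene or within 2 kb, against 22.3% of other protein-coding genes (odds ratio 7.58, 95% interval 4.88 to 11.8, exact adjusted p = 8.38e-20), and the replicates' own top peaks gave 67.0 ± 6.18% (SD, n = 3). The 63 genes drew on 72 distinct peaks, 60 of the genes had a summit within 1 kb of their own TSS, and the median distance of the nearest summit was 30 bp. The other protein-coding genes were not matched on expression or on open promoters. Enrichment of open promoters by any immunoprecipitation therefore cannot be told apart here from binding by NK7.1. RpS27 had a summit 24 bp upstream of its TSS with a signal of 673, RpL14 one 27 bp upstream with 434, and RpL7 one in its 5' UTR with 399.

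Notch pathway and E(spl) complex genes, which include clustered bHLH repressor genes, had peaks at 8 of 17 members (47.1%, odds ratio 3.05, 95% interval 1.18 to 7.92), which did not pass the threshold (exact adjusted p = 0.0919). Named members were E(spl)m8-HLH (signal 419, at a peak 134 bp upstream of gro), N itself (245, intron), E(spl)malpha-BFM (211) and E(spl)mdelta-HLH (133, in an intron of CG43116), and Delta had no peak. The replicates' own top peaks gave 39.2 ± 8.99% (SD, n = 3). With gene length as a covariate the list passed the threshold (odds ratio 3.42, likelihood-ratio chi-square test, adjusted p = 0.0436), while the odds ratio was 1.91 for summits within 1 kb of a TSS and 1.42 for the 1237 strongest peaks (exact adjusted p = 0.609 and 0.863). Of the signalling ligands and receptors, 11 of 27 (40.7%) had a peak, at an odds ratio of 2.36 that did not pass the threshold (exact adjusted p = 0.0919). They included the EGF receptor ligand spi (451) and its antagonist aos (337), the Wnt receptor fz (302) and the FGF ligand ths (242). Without replicate 3 the list passed the threshold (exact adjusted p = 0.0251). The odds ratio was 1.15 with gene length as a covariate (likelihood-ratio chi-square test, adjusted p = 0.735) and 1.41 for summits within 1 kb of a TSS, where the exact test gave an adjusted p of 0.670.

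Receptor and cuticle gene families carried few peaks. They too were compared with all other protein-coding genes, unmatched on expression, so the low shares need not reflect a choice of sites by NK7.1. Of 119 odorant and gustatory receptor genes, 5 (4.20%) had a summit in the window (odds ratio 0.149, exact adjusted p = 3.43e-07), and only 1 of the 5 had a summit within 1 kb of its own TSS. The peak counted for Or85f, with a signal of 320, lay 77 bp upstream of RpL34b, and that for Gr94a (217) lay 38 bp upstream of p53. Those for Gr97a (116) and Or88a (98.9) had Tsp97E and CG12402 as nearest TSS. Of 70 cuticle protein genes, 3 (4.29%) had a summit in the window (odds ratio 0.153, exact adjusted p = 0.000177), none of them within 1 kb of its own TSS. These were Cpr76Ba (241), Cpr31A (154, in an intron of Pen) and Cpr47Eg, whose peak (101) is also the one named for TpnC47D.

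For developmental regulators no list differed past the threshold in Fisher's exact test, and 2 of them did with gene length as a covariate, an alternative also fixed beforehand. Of 20 NK-like homeobox genes only NK7.1 itself had a peak (5%, odds ratio 0.180, exact adjusted p = 0.136). With gene length as a covariate this list was lower (odds ratio 0.108, likelihood-ratio chi-square test, adjusted p = 0.00812). Neural progenitor and glial regulators had peaks at 2 of 24 genes, pros (165) and SoxN (101), at an odds ratio of 0.311 (exact adjusted p = 0.258). They too were lower with gene length as a covariate (odds ratio 0.215, likelihood-ratio chi-square test, adjusted p = 0.0335). The Hox complex had peaks at 2 of 12 genes, bcd (152) and Antp (145), with an adjusted p of 1.00. Segmentation genes had peaks at 3 of 24, namely nkd (157), ptc (142) and cad (137), with an adjusted p of 0.536. Mesoderm and muscle regulators had peaks at 8 of 29 (exact adjusted p = 0.733), the strongest counted for Mef2 (755) and lying 148 bp upstream of Pal1, followed by zfh1 (251), org-1 (194) and tup (173), whose peak lay 122 bp upstream of CG10602.

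Among lists of differentiated cells, muscle structural genes had peaks at 4 of 18, namely Msp300 (377), Zasp52 (231), sls (223) and TpnC47D (101), with an adjusted p of 1.00. Neuron differentiation genes had peaks at 4 of 19, also with an adjusted p of 1.00. These were elav (361), nSyb (133, 203 bp upstream of Bgb), and ChAT and VAChT, which share 1 peak (165). Tracheal and ectodermal regulators had peaks at 4 of 15, rib (158), peb (147), ct (132) and bnl (115), with an adjusted p of 0.984.

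**Figure D4:**
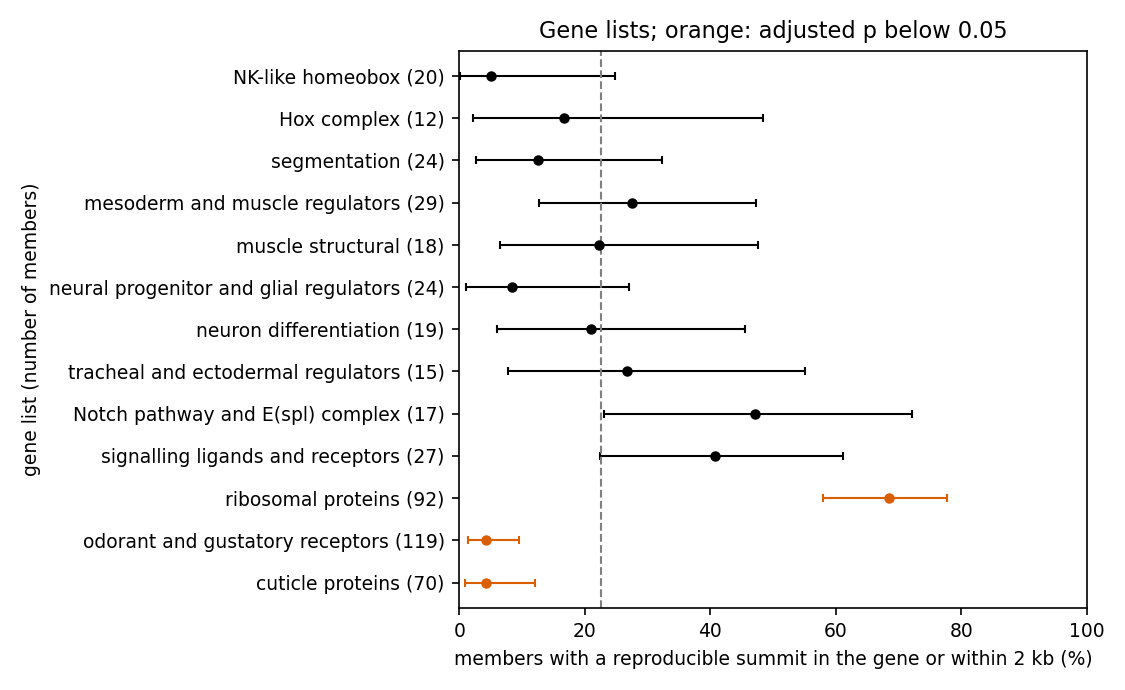
Share of members of each fixed gene list, in percent, with a reproducible summit in the gene or within 2 kb, with exact 95% intervals. The dashed line marks the 22.6% of all protein-coding genes, and orange marks the 3 lists past the threshold, of which ribosomal proteins stood highest at 68.5%.

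Sequence at the summits was AT-rich. The median GC content within 50 bp of reproducible summits was 35.6%, against 43.1% in the flanks 500 bp away, whereas low-ranked summits had 44.6% and their flanks 42.1%. The replicates' own top peaks had a median of 36.6 ± 1.98% (SD, n = 3). Of 2080 6-mers, 366 were more frequent at summits than flanks and 522 less frequent, counting only those past the threshold in the exact McNemar test. Of the 228 6-mers with at most 1 G or C, 195 were among the more frequent. The leading one, TTAAAA, was found at 26.2% of summits and 14.2% of flanks (odds ratio 2.12, exact adjusted p = 4.78e-22).

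TAATTG, chosen beforehand as a homeodomain core, was found at 235 of 2475 summits (9.49%) and in as many flanks, an odds ratio of 1.00 (95% interval 0.820 to 1.22, exact adjusted p = 1.00). Whether it is the core that NK7.1 itself prefers was not tested. In the replicates' own top peaks it was found at 9.66 ± 1.47% of summits and 9.48 ± 0.897% of flanks (SD, n = 3), and the direction varied, with 11.3% against 8.53% in replicate 1, 9.29% against 10.3% in replicate 2 and 8.40% against 9.62% in replicate 3. Against low-ranked summits, which were richer in GC, it was more frequent (odds ratio 1.25, exact adjusted p = 0.00733). TAATTA was found at 6.95% of summits and 5.41% of flanks (odds ratio 1.31, exact adjusted p = 0.0685), and it passed the threshold among the 1237 strongest peaks (odds ratio 1.69, exact adjusted p = 0.00667). It also passed without replicate 2 (exact adjusted p = 0.00201), without replicate 3 (exact adjusted p = 0.00922), with windows of 100 bp and against low-ranked summits. With windows of 25 bp (exact adjusted p = 0.232) and without replicate 1 (exact adjusted p = 0.152) it did not. In the replicates' own top peaks TAATTA was found at 7.92% of summits against 5.86% of flanks in replicate 1, 7.15% against 6.91% in replicate 2 and 6.51% against 6.14% in replicate 3. In the full set all 13 other 6-mers of the same base composition had an odds ratio at least as high as its 1.31, with a median of 1.75. There it did not stand out from the AT-rich sequence at summits. The 6-mers of the same composition were not compared among the 1237 strongest peaks. GAGAG, the core bound by GAGA factor, was less frequent at summits than flanks, at 292 against 371 of 2475 windows (odds ratio 0.761, exact adjusted p = 0.00609). That difference was not past the threshold with windows of 25 bp (exact adjusted p = 0.232) or 100 bp (exact adjusted p = 0.960), nor against low-ranked summits (exact adjusted p = 0.130). Summits were poorer in GC than flanks, and GAGAG was not compared with words of the same base composition. Its lower share therefore need not be particular to this motif. In a split made after the data were seen, GAGAG passed the threshold away from a TSS (odds ratio 0.681, exact adjusted p = 0.0423) and not near one (odds ratio 0.807, exact adjusted p = 0.113). For CAGGTA and CACGTG the odds ratios of 0.945 and 0.867 did not pass the threshold (exact adjusted p = 1.00 for both). In the same split CACGTG was found at 5 summits and 17 flanks away from a TSS (odds ratio 0.294, exact adjusted p = 0.0423) and at 21 summits and 13 flanks near one (odds ratio 1.62, exact adjusted p = 0.382). Words of the same base composition were not compared within the split.

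**Figure D5:**
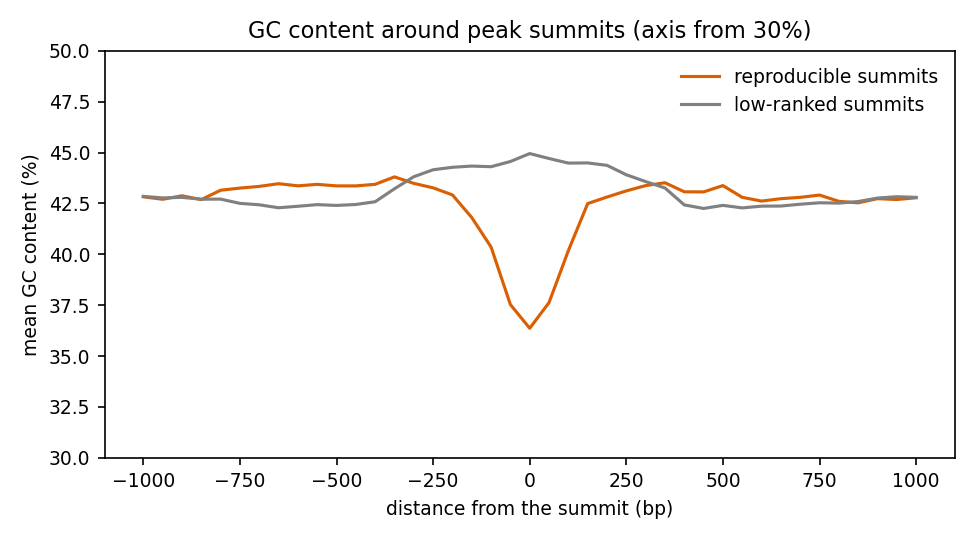
Mean GC content, in percent on an axis that starts at 30%, in 51 bp windows by distance in bp from reproducible (orange) and low-ranked (grey) summits. At the summit the reproducible peaks fell to 36.4% while the low-ranked peaks stood at 44.9%.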

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

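The dm3 lists hold peaks on sequences outside the 6 chromosome arms, which were used only in the sizes of the lists. They numbered 51 in the pooled list and 115, 142 and 48 in the lists of replicates 1, 2 and 3. These numbers are above the 3 that a count of 0 allows, but 0 was not an expected count here. None of these peaks was in the reproducible set of that build. They were noted because they lie in data outside the comparisons. Peaks can be called on unplaced and heterochromatic sequence, and no control list was used here, so the count does not show enrichment there.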

How the results depend on the processing

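Replicates left out in turn for pairs, and the dm3 build, were chosen after seeing the data; all other alternatives were planned. Of 240 results under alternatives, 176 were counted as unchanged, 9 no longer passed the threshold, 11 newly passed it, 26 changed direction and 18 untested values moved. Unchanged tests kept their direction and side of the threshold, and pairwise overlap without each replicate stayed within the spread. The 176 also include summary counts that shifted. With a TSS window of 500 bp 4 features passed the threshold, against 6, and dm3 held 2273 reproducible peaks, against 2475. The near-TSS, coding exon, 3' UTR and intergenic differences and the ribosomal, receptor and cuticle lists kept direction and side throughout, although their sizes varied. The odds ratios were 2.20 to 6.19 for near-TSS summits (highest against random positions), 5.68 to 12.0 for ribosomal, 0.0520 to 0.287 for receptor and 0.0437 to 0.206 for cuticle genes. The depth of the libraries is unknown, so what it limits could not be assessed. No paired analysis was possible because the series holds 1 group. Except where an alternative's construction sets the value, the cause was not tested.

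Support by all 3 replicates (57.7%) was 86.1% with the doubled number of top peaks, 99.3% with all listed peaks, 50.6% with summits within 100 bp, 47.6% with 50% reciprocal overlap and 93.5% for the 1237 strongest peaks. Support by both remaining replicates was 66.3 to 67.0% when each replicate was left out, which asks for fewer lists. The peaks so supported are the subsets behind the values without each replicate for arms, features, gene lists and motifs. Pairwise overlap (68.7%) was 60.7% with summits within 100 bp, 64.3% with reciprocal overlap, 73.4% with 1237 peaks and 61.7% with the doubled number, and 68.4 to 69.3% without each replicate. The reproducible set held 2273 peaks in dm3.

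On the arms, the 2L odds ratio (0.976) was 1.08 for the strongest peaks, 1.05 against arm length and 0.994 to 1.01 without each replicate. The 3R one (0.970) was 1.00 against arm length. Against arm length chromosome 4 had 0.399 and X 1.05. The 5' UTR odds ratio (0.249) was 0.661 with a TSS window of 500 bp, 0.185 with 2 kb, 0.332 for the strongest peaks and 0.247 to 0.375 without each replicate, the highest without replicate 1 (exact adjusted p = 0.0903). The intron odds ratio was 0.948 with 500 bp.

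For gene lists with summits within 1 kb of a TSS, the odds ratios were 0.221 for mesoderm and muscle regulators, 1.24 for muscle structural genes and 0.443 for tracheal and ectodermal regulators. Among genes with a listed peak the tracheal and ectodermal regulators had 0.921. With gene length as a covariate 6 lists passed the threshold instead of 3, and the odds ratios were 3.42 for the Notch list, 0.108 for NK-like homeobox genes, 0.789 for mesoderm and muscle regulators, 0.215 for neural progenitor and glial regulators and 0.643 for tracheal and ectodermal regulators. For the strongest peaks they were 1.33 for the Hox complex and for muscle structural genes and 1.24 for neuron differentiation. Without each replicate the range was 1.02 to 1.04 for the Hox complex and for muscle structural genes, 1.36 to 1.39 for neuron differentiation and 2.16 to 3.02 for signalling genes, the highest without replicate 3.

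Of the 5 motifs, 1 passed the threshold; with 25 bp windows 0 did, and 2 did against low-ranked summits and for the strongest peaks, and 1 to 2 without each replicate. GAGAG had odds ratios of 0.823 with 25 bp, 0.955 with 100 bp and 0.891 against low-ranked summits. TAATTG had 1.25 against low-ranked summits. TAATTA had 1.31 with 100 bp (exact adjusted p = 0.0132), 1.33 against low-ranked summits, 1.69 for the strongest peaks and 1.34 to 1.68 without each replicate. CAGGTA had 1.05 and CACGTG 1.02 with 100 bp, and CACGTG 1.14 for the strongest peaks.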

Other observations

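The gene families in this paragraph, the tests of TAATTG, open promoters, extra copies, long genes and TATCGATA, and the matched 6-mers were chosen after the results they concern were seen, while those on GC content, divergent pairs, GGTCACAC and distance were written before their own values were known. The comparison matched on distance was added once the divergent-pair and TATCGATA results were known. The families were picked after a scan of all gene symbol prefixes with many members and TATCGATA from the ranking of 6-mers, and the p-values given for them do not account for that choice. The conditions that would exclude TAATTG or a long gene were reworded after the first values, and tests of divergent pairs, TATCGATA and GGTCACAC as reasons for the near-TSS preference were dropped, because their outcome was fixed by the choice of near-TSS summits or by counts already known. Of families picked for few peaks, 0 of 35 UDP-glycosyltransferase genes (exact adjusted p = 0.00155), 0 of 25 Osiris genes (exact adjusted p = 0.00870) and 4 of 60 ionotropic receptor genes (6.67%, odds ratio 0.244, exact adjusted p = 0.00759) had a summit in the gene or within 2 kb, by Fisher's exact test over 9 families. For summits within 1 kb of a TSS the adjusted p was 0.0514, 0.0986 and 0.00205 in the same order. Serpin genes had 3 of 27 (exact adjusted p = 0.316).

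Of other families, mitochondrial ribosomal protein genes had 22 of 73 (30.1%, odds ratio 1.48, exact adjusted p = 0.185), although mRpL41, mRpS10 and mRpS23 were counted at the peaks ranked 8, 10 and 17, of which the peak of mRpS10 is the one nearest to Art3. Translation initiation factors had 15 of 44 (34.1%, exact adjusted p = 0.162), vacuolar sorting genes 10 of 27 (37.0%, exact adjusted p = 0.184), proteasome subunits 11 of 48 (22.9%, exact adjusted p = 1.00) and respiratory complex I 7 of 40 (17.5%, exact adjusted p = 0.642). Whether the ribosomal share differs from that of each family was not tested.

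Reproducible summits lay near a TSS more often than low-ranked ones. Low GC content as the reason is argued against: low-ranked summits matched on GC had a near-TSS share of 41.6% on average and 44.2% at most over 100 draws, against 65.6%. Whether binding through TAATTG is the reason was not decided. Its condition was reworded after the first values, and the test did not compare near-TSS summits with other summits. All 59 other 6-mers of the same composition had an odds ratio at least as high as its 1.00. Their median was 1.57, and against low-ranked summits all 59 were at least as high too. TAATTG was thus not raised at summits beyond other 6-mers of its composition. It was found at 8.81% of reproducible summits near a TSS and 10.8% of those away from one. Enrichment of open promoters by any immunoprecipitation, which could give the odds ratio of 2.48 without any binding by NK7.1, cannot be told apart from recruitment of NK7.1 to promoters, because libraries of an untagged line or another factor were not analysed here. No biological difference between groups was tested, since the design has 1 group.

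The 7 reproducible peaks at NK7.1 exceeded what its length would give: 2 of 329 other genes within 25% of its length had as many (0.608%, 95% interval 0.0737 to 2.18%), and 50 of 10000 random windows of 47539 bp did. The 7 include peaks that not every replicate supported, and the count was not repeated without them. Extra copies of the locus in the tagged line may also raise signal there and remain open. The locus held 8 low-ranked peaks, the same as the median of random windows, which neither shows nor rules out a raised background. At 2 times the lowest reproducible signal 2 of the 7 peaks would remain, and 23.0% of random windows held as many as 2 at the plain threshold. This is the level a doubled copy number would need if the signal value rose in proportion to copies, which was not tested. Under that assumption the excess would not be unusual.

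Divergent pairs were counted as TSSs of protein-coding genes on both strands within 1 kb of a summit, in either order. Among near-TSS summits alone, 558 of 1623 reproducible (34.4%) and 22.7% of low-ranked ones had such a pair. The odds ratio was 1.79 (95% interval 1.60 to 2.00, exact adjusted p = 1.35e-22). Reproducible summits also lay closer to a TSS of a protein-coding gene, at a median of 156 bp against 308 bp. Low-ranked summits matched on that distance had 27.3% on average and 31.0% at most, so distance went with part of the difference and was not excluded for the rest by the margin set in advance. TATCGATA was found within 100 bp of 5.05% against 3.40% (odds ratio 1.51, exact adjusted p = 0.00241), and draws matched on distance reached 5.85%. GGTCACAC was found at 2.40% against 2.72% (odds ratio 0.882, exact adjusted p = 0.509).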
